A study of Homo sapiens with 60 samples.

How the data were processed

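The data are 60 RNA-seq libraries of HT29 cells in 25 groups of n = 1 to 3. Per the labels' protocols, total RNA (1 µg, RIN above 7) was made into libraries with the MGIEasy RNA Directional kit and sequenced as 100 bp paired reads on an MGIseq instrument. The authors deposited 1 table of the series with an RSEM expected count per Ensembl gene (60675 genes) and library. Per the submitters' processing notes, the reads passed FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 on hg38. The release of the annotation, the strand setting of RSEM and any filter on genes are not given in the sources used here. The table also has 210 columns of samples outside this series' groups, not used here. The labels give the vehicle as 0.1% DMSO, the series text 2%. The series text says that samples with low RNA were left out by the authors and that extracts with an IC20 below 500 µg/mL were given at the IC20 and its 1/5 and 1/25 dilutions.

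Columns were matched to samples by the codes in the labels. Vehicle has a code set of its own, Sayeok-tang and Bojungikgi-tang share code set 8, the ginger extracts 9, Pinelliae Tuber and Scutellariae Radix 10, and Coptidis Rhizoma and Zizyphi Fructus 11. Each contrast with vehicle is thus also a contrast of code sets. Of the values, 90.0% to 92.1% per library were whole numbers. Expected counts were rounded to whole numbers, and 34632 genes had a count. A gene at 1 CPM has 18 to 36 counts. Symbols and positions were taken from GENCODE 29 on GRCh38, which holds 56996 of the IDs.

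The comparisons, their tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The main fit took the 54 libraries of the 19 groups with n of 2 or 3 and used edgeR 4.0.16 in R 4.3.3: filterByExpr by group (16763 genes), TMM, estimateDisp without tagwise values, glmQLFit with robust = TRUE and glmQLFTest, with Benjamini-Hochberg at 0.05. It had 35 residual degrees of freedom, a common biological coefficient of variation of 0.0855 and a median prior df of 6.58. The SE of a log2 fold change is its size over the root of F. Coptidis Rhizoma and Zizyphi Fructus were each taken as 1 group of 3 doses against vehicle in a fit of 6 libraries. For their single libraries, log2 ratios to the vehicle mean used a pseudocount of 0.5 CPM, and list medians were placed among 10000 random lists matched on expression.

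For 27 gene lists (492 members) camera of limma 3.58.1 was run with a preset correlation of 0.01 and Benjamini-Hochberg over the lists, and with an estimated correlation as the alternative. Running it beyond the contrasts of high dose with vehicle and with low dose was chosen after the data were seen. Members were counted as rising or falling at an adjusted p under 0.05 over all genes, and again adjusted over the list alone. Genes with near-identical copies (AKR1C1, AKR1C2 and AKR1C3, the UGT1A genes, pseudogenes) share reads.

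Named genes are the 5 largest rises and falls of each comparison with a call, an average log2 CPM above 2, a symbol, and every library of one group beyond every library of the other; up to 4 members of each list described with the smallest p; and a panel of 31 genes. Some genes that these rules select are not reported here, though tests and counts of whole lists include them. For single libraries they are genes with a log2 ratio above 1 in size and the same sign at 3 doses, up to 5 each way, and a mean log2 CPM above 2, a limit added after the data were seen.

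The scripts were tested on simulated data made from these libraries. In the main fit at the size of Sayeok-tang high dose against vehicle, 93% of 100 genes changed 1.5-fold and 100% of those changed 2-fold were called, and 2.0% of calls were unchanged genes (16559 genes). For the interaction these were 66%, 98% and 4.7%, and for the fit of 6 libraries 82%, 100% and 8.5%. Changes that vary by dose were not simulated. Of the lists, the 1 raised was called, and 0 of 26 random lists.

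The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, only the libraries compared, a replicate number as block (also within code set) and each library left out in turn. A fit without the 3 libraries that stand apart, and that of only the libraries compared at the medium and low dose, were added after the data were seen. In the main fit these 3 lie over 10 median absolute deviations from the median mitochondrial or ribosomal protein share. They are vehicle replicate 1 (7.08% ribosomal, 13.5 deviations), Pinelliae Tuber high-dose replicate 2 (14.3% mitochondrial, 18.1) and Scutellariae Radix low-dose replicate 3 (9.20% ribosomal, 31.9). Coptidis Rhizoma low dose (15.2% mitochondrial) is outside it. Whether replicate numbers pair the samples was checked from the correlation of same-numbered libraries after group means were removed. Each was above 0.1 in Pinelliae Tuber medium dose against vehicle (0.122 to 0.151), low dose against vehicle (0.183 to 0.569) and fresh against dried ginger at the low dose (0.247 to 0.288), where the pairing comes from the data alone. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.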

Results

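Total RNA of HT29, a human colorectal adenocarcinoma cell line, was sequenced after 24 h with 1 of 8 extracts of digestive herbal medicines or with vehicle. The 60 libraries fall into 25 groups. Vehicle had n = 3. The water extracts were Sayeok-tang (n = 3 per dose) and Bojungikgi-tang (n = 2 per dose), both multi-herb formulas. The 70% ethanol extracts with n = 3 per dose were Zingiberis Rhizoma Recens (fresh ginger), Zingiberis Rhizoma (dried ginger), Pinelliae Tuber and Scutellariae Radix (skullcap root). Coptidis Rhizoma and Zizyphi Fructus (jujube fruit), also in ethanol, had n = 1 per dose. Doses were 500, 100 and 20 µg/mL, and 320, 64 and 12.8 µg/mL for Coptidis Rhizoma. Libraries held 18.02 to 35.82 M counts (M, 1e6, median 24.46 M) and 20872 to 23682 genes with a count. In the main fit 3 of 54 stand apart in mitochondrial or ribosomal protein share.

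The question put to each extract is how it changes gene expression in these cells, and whether the change grows with dose. Values of genes are log2 fold changes ± SE unless a unit is named, camera p-values are adjusted over the lists of a comparison, and counts of genes called are at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test over 16763 genes. Counts within the list are at a p adjusted over its members alone. Genes whose call ended with 1 replicate left out are followed by the values without it and by those replicates. Between extracts, a gene that rose is higher in the extract named first. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries.

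**Figure D1:**
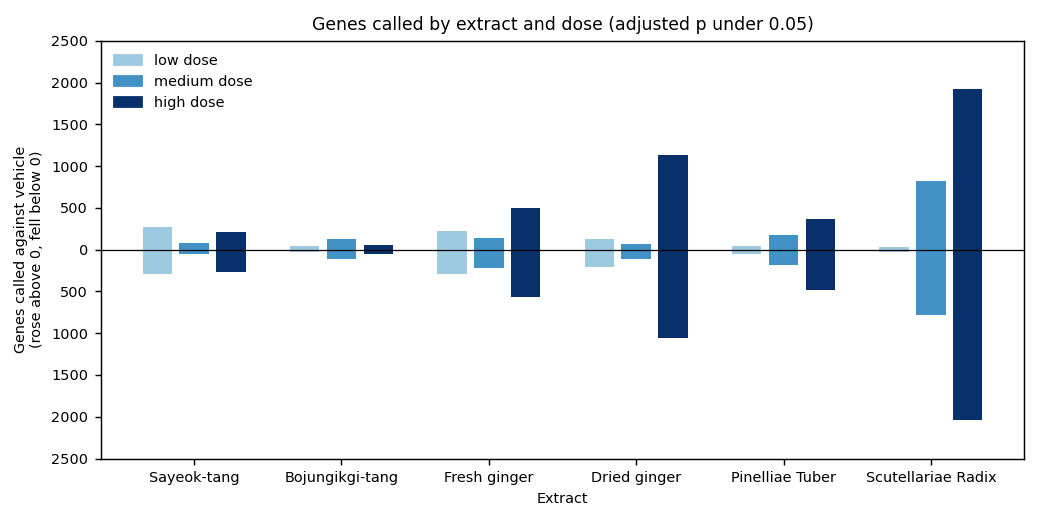
Number of genes called against vehicle (y axis, genes that rose above 0 and genes that fell below 0) for the 6 extracts with 2 or 3 libraries per dose, by dose (x axis). The bars of Scutellariae Radix at the high dose reach 1920 genes that rose and 2035 that fell.

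Sayeok-tang at the high dose raised chemokine genes (n = 3 against 3). CXCL1 (3.88 ± 0.20, adjusted p = 1.5e-18) stood at 1.53 ± 0.891 CPM (mean ± SD) in vehicle and 21.01 ± 1.65 CPM in treated cells. CXCL8 (2.50 ± 0.11, adjusted p = 8.9e-21) stood at 4.74 ± 0.270 and 26.6 ± 1.84 CPM. On chromosome 4 of GRCh38, CXCL1 (ENSG00000163739) spans 73869393 to 73871242 and CXCL8 (ENSG00000169429) 73740506 to 73743716. CCL20 (4.46 ± 0.27), CXCL3 (2.15 ± 0.24), the protease inhibitor PI3 (1.84 ± 0.16) and BIRC3 (0.87 ± 0.10), an apoptosis inhibitor under NF-kB control, rose as well. Of 16 NF-kB and cytokine genes tested, 10 rose and 0 fell (11 and 0 within the list, camera adjusted p = 2.0e-25). The test called 477 genes, 212 rose and 265 fell.

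CYP1A1 (1.70 ± 0.33), UGT1A6 (0.51 ± 0.07), CYP1B1 (0.47 ± 0.08) and TIPARP (0.41 ± 0.08) rose among targets of the aryl hydrocarbon receptor (AhR), the sensor of planar aromatic compounds. Of 11 AhR targets tested, 5 rose and 0 fell (7 and 0 within the list, camera adjusted p = 1.3e-06). Of NRF2 targets, the antioxidant program, GCLC (0.39 ± 0.07), AKR1C1 (0.48 ± 0.09), TXNRD1 (0.35 ± 0.07) and SLC7A11 (0.41 ± 0.12) rose. Of 24 NRF2 targets tested, 5 rose and 0 fell (10 and 0 within the list, camera adjusted p = 1.2e-05). Of replication genes MCM4 (0.19 ± 0.04) and RRM2 (0.17 ± 0.04) rose slightly. Of 25 DNA replication genes tested, 2 rose and 0 fell (5 and 1 within the list, camera adjusted p = 0.00477). Secretory cell markers REG4 (-0.63 ± 0.09) and TFF3 (-0.63 ± 0.14) fell, the enterocyte marker CEACAM7 (2.03 ± 0.30) rose and VIL1 (-0.20 ± 0.04) fell, and the stem cell marker LGR5 (0.34 ± 0.08) rose. Of 13 secretory markers tested, 0 rose and 2 fell (0 and 3 within the list, camera adjusted p = 0.00138). Of 13 enterocyte markers tested, 1 rose and 1 fell (1 and 2 within the list, camera adjusted p = 0.860). Other falls were MTND4P12 (-1.21 ± 0.25), MALAT1 (-1.12 ± 0.14), HMGB1P6 (-1.0 ± 0.21), MT-ND6 (-0.93 ± 0.26) and BCYRN1 (-0.85 ± 0.21). MTND4P12 and HMGB1P6, copies of MT-ND4 and HMGB1, are uncertain. Of 18 groups of 6 extracts against the same vehicle, low doses included, MTND4P12 was called lower in 18, MALAT1 in 17, and BCYRN1 and FAM215B in 14. HMGB1P6 and REG4 were lower in 13, AURKA and RPLP1 in 12, SLC16A1-AS1 and TMEM256 in 10, and LGR5 higher in 12. These are not specific to an extract and may stem from the vehicle. Of 32 ribosomal protein genes tested, 0 rose and 1 fell (0 and 1 within the list, camera adjusted p = 5.2e-06, adjusted p = 0.390 with an estimated correlation). RPLP1 (-0.63 ± 0.16) fell. The count of 477 genes was 1016 with no low-count filter and 1368 without the 3 that stand apart. It was 191, 206 and 194 without high-dose replicate 1, 2 and 3 and 140 and 231 without vehicle replicate 1 and 2. Of the 27 genes named here with a call, 16 kept it with each library left out in turn, and it ended for MCM4 (0.17; vehicle 2), RPLP1 (-0.67 to -0.45; high 1, 2 and 3, vehicle 1), LGR5 (0.31 to 0.32; vehicle 1 and 2), CYP1A1 (1.27; vehicle 2), SLC7A11 (0.37 to 0.46; high 1, 2 and 3, vehicle 1 and 2), TFF3 (-0.55 to -0.50; high 1, vehicle 1), RRM2 (0.14 to 0.18; high 1, 2 and 3, vehicle 1 and 2), MT-ND6 (-1.04 to -0.54; high 1, 2 and 3, vehicle 1 and 2), BCYRN1 (-0.80 to -0.50; high 1 and 2, vehicle 1), MTND4P12 (-0.72; vehicle 1) and HMGB1P6 (-0.75; vehicle 1).

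Against its own low dose, Sayeok-tang called 64 genes (16 rose, 48 fell). ALDH3A1 (0.71 ± 0.10, adjusted p = 1.6e-04), AKR1C1 (0.58 ± 0.09), AKR1B10 (0.58 ± 0.09), AKR1C2 (0.57 ± 0.10) and CYP1A1 (1.73 ± 0.34) rose. Among 24 NRF2 targets tested, 4 rose and 0 fell (15 and 0 within the list, camera adjusted p = 1.0e-25). Interferon-induced antiviral genes OAS2 (-0.93 ± 0.20), MX1 (-0.77 ± 0.16), OAS1 (-0.48 ± 0.09) and HERC6 (-0.61 ± 0.14) fell, as did ADH6 (-0.74 ± 0.12) and SLC14A1 (-0.62 ± 0.11). Of 20 interferon genes tested, 0 rose and 7 fell (0 and 15 within the list, camera adjusted p = 6.3e-27). CXCL1 (0.43 ± 0.15) and CXCL8 (0.34 ± 0.10) did not pass this test. With 1 replicate left out the call ended for OAS1 (-0.40 to -0.39; high 2, low 1), OAS2 (-1.0 to -0.75; high 1, 2 and 3, low 1 and 3), HERC6 (-0.68 to -0.52; high 1, 2 and 3, low 1 and 3), CYP1A1 (1.54 to 1.65; high 3, low 1 and 2) and MX1 (-0.79 to -0.60; high 2 and 3, low 1). The medium and low doses against vehicle called 133 and 554 genes. There the interferon list lay above vehicle, with OAS2 (1.10 ± 0.20) and IFI44 (0.83 ± 0.13) at the medium dose and OAS2 (1.15 ± 0.20) at the low dose. Among 20 interferon genes tested at the medium dose, 10 rose and 0 fell (15 and 0 within the list, camera adjusted p = 2.0e-21). Interferon genes that rose at the low dose were 12 and that fell 0 of 20 tested (14 and 0 within the list, camera adjusted p = 1.7e-14). CXCL1 read 4.04 ± 0.20 and 3.45 ± 0.20. The high against low count was 104 with DESeq2, 124 with no low-count filter and 519 with only the libraries compared. It was 25, 19 and 27 without high-dose replicate 1, 2 and 3 and 27, 27 and 23 without low-dose replicate 1, 2 and 3. The medium count was 451 with no low-count filter and 554 without the 3 that stand apart. It was 62, 72 and 55 without medium-dose replicate 1, 2 and 3 and 51 and 65 without vehicle replicate 1 and 2. The low count was 1417 with no low-count filter, 1059 with only the libraries compared and 1724 without the 3 that stand apart. It was 82, 170 and 123 without low-dose replicate 1, 2 and 3 and 55, 261 and 1009 without vehicle replicate 1, 2 and 3.

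In Bojungikgi-tang at the high dose (n = 2 against 3) CXCL1 (4.34 ± 0.21, adjusted p = 8.2e-20) reached 28.8 ± 0.0607 CPM and CXCL8 (2.75 ± 0.12) 31.8 ± 0.317 CPM, with CCL20 (4.91 ± 0.28), PI3 (2.53 ± 0.16) and BIRC3 (1.08 ± 0.10) also higher. Among 16 NF-kB and cytokine genes tested, 7 rose and 0 fell (12 and 0 within the list, camera adjusted p = 2.2e-33). AhR targets CYP1A1 (2.44 ± 0.31), CYP1B1 (0.75 ± 0.08), ALDH1A3 (0.44 ± 0.08) and UGT1A6 (0.43 ± 0.07) rose. Among 11 AhR targets tested, 5 rose and 0 fell (6 and 0 within the list, camera adjusted p = 4.2e-12). Of cholesterol genes MVK (-0.33 ± 0.08) fell, while INSIG1 (-0.18 ± 0.06) and FDPS (-0.25 ± 0.08) missed the threshold. Of 21 cholesterol genes tested, 0 rose and 1 fell (0 and 5 within the list, camera adjusted p = 1.7e-04). RRM2 (0.27 ± 0.05) of the replication list, HSPH1 (0.23 ± 0.06) of the heat shock list, CEACAM7 (2.15 ± 0.32) and LGR5 (0.37 ± 0.08) rose. Among 25 DNA replication genes tested, 1 rose and 0 fell (5 and 0 within the list, camera adjusted p = 3.5e-05). Of 15 heat shock genes tested, 1 rose and 0 fell (2 and 0 within the list, camera adjusted p = 0.0418, adjusted p = 0.0728 with an estimated correlation). Of the interferon list IFI44 (0.57 ± 0.14) rose. In all, 1 rose and 0 fell of 20 interferon genes tested (2 and 0 within the list, camera adjusted p = 0.00197, adjusted p = 0.291 with an estimated correlation). MTND4P12 (-1.10 ± 0.27) (uncertain), MALAT1 (-0.91 ± 0.16), FAM215B (-0.86 ± 0.17), IGFL2-AS1 (-0.80 ± 0.17) and SLC16A1-AS1 (-0.71 ± 0.16) fell; counting by strand is not given in the sources used here, so antisense genes are uncertain. The test called 105 genes (56 rose, 49 fell). The count was 178 with DESeq2, 367 with no low-count filter, 30 with only the libraries compared and 412 without the 3 that stand apart. It was 37 and 34 without high-dose replicate 2 and 3 and 49 and 57 without vehicle replicate 1 and 2. Of the 20 genes named here with a call, 8 kept it with each library left out in turn, and it ended for MVK (-0.36 to -0.25; high 2 and 3, vehicle 1), HSPH1 (0.20 to 0.25; high 2 and 3, vehicle 1 and 2), IFI44 (0.46 to 0.63; high 2 and 3, vehicle 1 and 2), LGR5 (0.33 to 0.41; high 2 and 3, vehicle 1 and 2), UGT1A6 (0.38; high 3), RRM2 (0.27; high 2), ALDH1A3 (0.41; high 2), SLC16A1-AS1 (-0.63 to -0.52; high 2, vehicle 1), FAM215B (-0.93 to -0.79; high 2 and 3), MTND4P12 (-1.34 to -0.60; high 2 and 3, vehicle 1), MALAT1 (-0.90; high 2 and 3) and IGFL2-AS1 (-0.61; high 2).

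Between its high and low doses 11 genes differed (n = 2 against 2). CYP1A1 (2.04 ± 0.34), CYP1B1 (0.69 ± 0.09, adjusted p = 6.0e-05), ALDH3A1 (0.67 ± 0.12), AKR1C2 (0.60 ± 0.12) and ALDH1A3 (0.59 ± 0.09) rose, and ADH6 (-0.68 ± 0.13), SLC6A20 (-0.50 ± 0.09) and ACSS2 (-0.38 ± 0.08) fell. With 1 replicate left out the call ended for ALDH3A1 (0.60 to 0.70; high 3, low 2 and 3), ACSS2 (-0.41 to -0.35; high 2 and 3, low 2 and 3), CYP1A1 (1.66 to 1.96; high 3, low 2), AKR1C2 (0.49 to 0.66; high 3, low 2 and 3), SLC6A20 (-0.53 to -0.44; high 2 and 3, low 3) and ADH6 (-0.76 to -0.59; high 2 and 3, low 2 and 3). AhR targets that rose were 5 and that fell 0 of 11 tested (7 and 0 within the list, camera adjusted p = 1.3e-25). In all, 0 rose and 0 fell of 20 interferon genes tested (0 and 0 within the list, camera adjusted p = 4.5e-11). At the medium and low doses 249 and 71 genes were called against vehicle. In all, 12 rose and 0 fell of 20 interferon genes tested at the medium dose (14 and 0 within the list, camera adjusted p = 8.8e-17). In all, 5 rose and 0 fell of 20 interferon genes tested at the low dose (12 and 0 within the list, camera adjusted p = 2.8e-14). The high against low count was 17 with DESeq2, 70 with no low-count filter and 323 with only the libraries compared. It was 6 and 2 without high-dose replicate 2 and 3 and 3 and 3 without low-dose replicate 2 and 3. The medium count was 1009 with no low-count filter, 41 with only the libraries compared and 1595 without the 3 that stand apart. It was 60 and 30 without medium-dose replicate 2 and 3 and 53, 124 and 603 without vehicle replicate 1, 2 and 3. The low count was 586 with no low-count filter, 29 with only the libraries compared and 444 without the 3 that stand apart. It was 25 and 22 without low-dose replicate 2 and 3 and 41 and 131 without vehicle replicate 1 and 3.

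Compared directly at the high dose, the water extracts differed in 1 gene, ALDH1A3 (-0.45 ± 0.08, adjusted p = 0.0169), a retinaldehyde dehydrogenase lower with Sayeok-tang. ALDH1A3 (-0.49 to -0.39; Bojungikgi-tang high 2 and 3, Sayeok-tang high 1 and 2) lost its call with 1 replicate left out. CXCL1 (-0.45 ± 0.16), CXCL8 (-0.25 ± 0.10) and CYP1A1 (-0.74 ± 0.26) missed the threshold, as did the rest, which does not show that the extracts act alike. NRF2 targets that rose were 0 and that fell 0 of 24 tested (1 and 0 within the list, camera adjusted p = 2.3e-05). Of 11 AhR targets tested, 0 rose and 1 fell (0 and 3 within the list, camera adjusted p = 0.0115, median 0.01 with the test pointing down). The count was 40 with no low-count filter, 14 with only the libraries compared and 0 with a replicate block within code set. It was 0 and 0 without Bojungikgi-tang high-dose replicate 2 and 3 and 0 and 0 without Sayeok-tang high-dose replicate 1 and 2.

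Fresh ginger at the high dose raised NRF2 targets and lowered interferon genes (n = 3 against 3). AKR1C2 (1.04 ± 0.10, adjusted p = 2.0e-09) went from 11.5 ± 1.14 to 23.6 ± 2.10 CPM, and AKR1B10 (0.82 ± 0.09), AKR1C1 (0.78 ± 0.09), GCLC (0.61 ± 0.07) and TXNRD1 (0.44 ± 0.07) rose with it. In all, 10 rose and 0 fell of 24 NRF2 targets tested (13 and 0 within the list, camera adjusted p = 4.2e-11). AKR1C genes share reads with near-identical copies, so the split between them is uncertain. CYP1A1 (1.62 ± 0.33), UGT1A6 (0.56 ± 0.07), CYP1B1 (0.51 ± 0.08) and ALDH3A1 (0.65 ± 0.10) rose among AhR targets, and HSPH1 (0.39 ± 0.05), HSPA8 (0.27 ± 0.04) and CHORDC1 (0.46 ± 0.09) among chaperones. In all, 7 rose and 0 fell of 11 AhR targets tested (7 and 0 within the list, camera adjusted p = 3.7e-07). Among 15 heat shock genes tested, 4 rose and 0 fell (7 and 0 within the list, camera adjusted p = 1.3e-04). IFIT1 (-0.88 ± 0.17), IFI6 (-0.85 ± 0.24), MX1 (-0.80 ± 0.17) and IRF9 (-0.69 ± 0.13), which interferon induces, fell. Of 20 interferon genes tested, 0 rose and 10 fell (0 and 15 within the list, camera adjusted p = 4.2e-11). Secretory markers REG4 (-0.78 ± 0.09), MUC13 (-0.38 ± 0.07) and TFF3 (-0.60 ± 0.14) fell, the cholesterol gene MVK (-0.32 ± 0.07) fell slightly, and so did the lysosomal proteases CTSB (-0.23 ± 0.06) and CTSD (-0.30 ± 0.08). Among 13 secretory markers tested, 0 rose and 5 fell (0 and 5 within the list, camera adjusted p = 3.0e-05). Among 21 cholesterol genes tested, 0 rose and 4 fell (0 and 7 within the list, camera adjusted p = 0.00386). Of 21 autophagy and lysosome genes tested, 0 rose and 5 fell (0 and 5 within the list, camera adjusted p = 0.00346). GPAT3 (0.81 ± 0.08), FAM157B (1.05 ± 0.30) and the efflux pump ABCC2 (1.08 ± 0.22) rose, and MTND4P12 (-1.26 ± 0.24) (uncertain), TMEM256 (-0.89 ± 0.19) and MALAT1 (-0.89 ± 0.14) fell, as in most groups. Of 14 drug metabolism genes tested, 5 rose and 1 fell (7 and 2 within the list, camera adjusted p = 5.6e-04). DNA replication genes that rose were 6 and that fell 0 of 25 tested (8 and 0 within the list, camera adjusted p = 0.00185). Of mitosis genes CCNB2 (-0.20 ± 0.06) and AURKA (-0.16 ± 0.05) fell. Of 25 mitosis genes tested, 0 rose and 3 fell (0 and 3 within the list, camera adjusted p = 0.0383, adjusted p = 0.0520 with an estimated correlation). The test called 1066 genes (502 rose, 564 fell). The count was 2435 without the 3 that stand apart. It called 462, 399 and 396 without high-dose replicate 1, 2 and 3 and 181 and 509 without vehicle replicate 1 and 2. Of the 30 genes named here with a call, 20 kept it with each library left out in turn, and it ended for AURKA (-0.18 to -0.12; high 1 and 2, vehicle 1, 2 and 3), MVK (-0.25; vehicle 1), CTSD (-0.32 to -0.25; high 1, 2 and 3, vehicle 1 and 2), IFI6 (-0.84 to -0.48; high 1 and 3, vehicle 1), CCNB2 (-0.20 to -0.16; high 1, 2 and 3, vehicle 1 and 3), TFF3 (-0.52; vehicle 1), CTSB (-0.20; high 3, vehicle 1), TMEM256 (-0.65; vehicle 1), FAM157B (0.72 to 1.03; high 1, vehicle 1 and 2) and MTND4P12 (-0.77; vehicle 1).

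High against low dose of fresh ginger called 82 genes (31 rose, 51 fell). AKR1C2 (1.20 ± 0.10, adjusted p = 4.3e-11), AKR1B10 (0.99 ± 0.09), AKR1C1 (0.90 ± 0.09), ALDH3A1 (0.85 ± 0.10) and CYP1A1 (1.37 ± 0.33) rose. In all, 9 rose and 0 fell of 24 NRF2 targets tested (17 and 0 within the list, camera adjusted p = 2.2e-37). SLC14A1 (-0.86 ± 0.10), MX1 (-0.81 ± 0.17), IFIT1 (-0.73 ± 0.18), CD200 (-0.67 ± 0.09), and BMF (-0.63 ± 0.12) fell. With 1 replicate left out the call ended for BMF (-0.55; high 1), CYP1A1 (1.17 to 1.29; high 1 and 2, low 1 and 2), MX1 (-0.82 to -0.74; high 1, 2 and 3, low 3) and IFIT1 (-0.80 to -0.66; high 1, 2 and 3, low 1, 2 and 3). Among 20 interferon genes tested, 0 rose and 3 fell (0 and 15 within the list, camera adjusted p = 3.7e-23). Against vehicle, 362 genes were called at the medium dose and 520 at the low dose. Among 25 mitosis genes tested at the low dose, 0 rose and 7 fell (0 and 10 within the list, camera adjusted p = 2.4e-05). The high against low count was 143 with DESeq2, 140 with no low-count filter and 214 with only the libraries compared. It was 39, 28 and 50 without high-dose replicate 1, 2 and 3 and 44, 47 and 36 without low-dose replicate 1, 2 and 3. The medium count was 1478 with no low-count filter, 29 with only the libraries compared and 1667 without the 3 that stand apart. It was 14, 15 and 62 without medium-dose replicate 1, 2 and 3 and 10, 99 and 966 without vehicle replicate 1, 2 and 3. The low count was 1482 with no low-count filter and 2026 without the 3 that stand apart. It was 201, 62 and 69 without low-dose replicate 1, 2 and 3 and 17, 210 and 1187 without vehicle replicate 1, 2 and 3.

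Dried ginger at the high dose raised NRF2 and amino acid stress genes and lowered secretory markers (n = 3 against 3). AKR1C2 (2.87 ± 0.10, adjusted p = 1.6e-25) reached 83.8 ± 4.01 CPM from 11.5 ± 1.14 CPM. AKR1C1 (2.48 ± 0.09), AKR1C3 (1.64 ± 0.15), AKR1B10 (1.68 ± 0.09), ABCC2 (2.45 ± 0.21) and GCLC (0.93 ± 0.07) rose too. In all, 20 rose and 0 fell of 24 NRF2 targets tested (20 and 0 within the list, camera adjusted p = 2.5e-35). Asparagine synthetase, ASNS (1.11 ± 0.06), stood at 130 ± 7.38 CPM against 60.3 ± 1.26 CPM, and CHAC1 (1.57 ± 0.16), TRIB3 (0.72 ± 0.07) and VLDLR (1.10 ± 0.12) rose with it. Of 20 ATF4 and amino acid response genes tested, 15 rose and 0 fell (15 and 0 within the list, camera adjusted p = 4.7e-18). HERPUD1 (0.54 ± 0.06), DNAJB9 (0.63 ± 0.10) and HSPA5 (0.35 ± 0.06) rose among ER chaperones. Of 17 ER chaperone genes tested, 8 rose and 0 fell (9 and 0 within the list, camera adjusted p = 1.5e-06). CYP1A1 (3.24 ± 0.26, adjusted p = 1.5e-12), ALDH3A1 (1.58 ± 0.10), UGT1A6 (0.79 ± 0.07) and CYP1B1 (0.71 ± 0.08) rose among AhR targets. In all, 8 rose and 0 fell of 11 AhR targets tested (8 and 0 within the list, camera adjusted p = 1.5e-14). The autophagy receptor SQSTM1 (0.93 ± 0.07) rose, and PDK4 (0.86 ± 0.09) and FABP1 (1.26 ± 0.17) rose in the fatty acid oxidation list. Among 21 autophagy and lysosome genes tested, 3 rose and 1 fell (7 and 2 within the list, camera adjusted p = 0.00538). Of 14 PPAR and fatty acid oxidation genes tested, 6 rose and 1 fell (9 and 2 within the list, camera adjusted p = 2.0e-05).

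REG4 (-1.51 ± 0.09, adjusted p = 1.4e-16), a secretory cell protein, fell from 27.9 ± 2.42 to 9.74 ± 0.771 CPM, with AGR2 (-0.71 ± 0.09) and TFF3 (-0.90 ± 0.14), while enterocyte markers CEACAM6 (0.74 ± 0.07) and KRT20 (0.46 ± 0.05) rose. Secretory markers that rose were 0 and that fell 6 of 13 tested (1 and 6 within the list, camera adjusted p = 8.1e-07). Among 13 enterocyte markers tested, 6 rose and 3 fell (7 and 4 within the list, camera adjusted p = 0.00538). CD200 (-1.56 ± 0.09), SLC14A1 (-1.53 ± 0.12), the Notch ligand DLL4 (-1.45 ± 0.14) and LINC00261 (-1.25 ± 0.11) were the other largest falls. Metallothioneins MT1X (-1.09 ± 0.24) and MT1E (-0.78 ± 0.18) fell. Of 7 metallothionein and zinc genes tested, 0 rose and 5 fell (1 and 5 within the list, camera adjusted p = 0.00582, adjusted p = 0.104 with an estimated correlation). MVK (-0.53 ± 0.07) fell in the cholesterol list, CCNB2 (-0.32 ± 0.06) in the mitosis list, and EPHB3 (-0.81 ± 0.11) among Wnt markers. Cholesterol genes that rose were 0 and that fell 8 of 21 tested (1 and 12 within the list, camera adjusted p = 7.1e-06). Mitosis genes that rose were 0 and that fell 5 of 25 tested (0 and 8 within the list, camera adjusted p = 0.00538). Of 14 Wnt and stem cell markers tested, 0 rose and 3 fell (0 and 5 within the list, camera adjusted p = 0.0597). Of 11 fatty acid synthesis genes tested, 3 rose and 0 fell (4 and 0 within the list, camera adjusted p = 0.00422, adjusted p = 0.120 with an estimated correlation). Of 18 p53 targets tested, 2 rose and 4 fell (2 and 4 within the list, camera adjusted p = 0.404, median 0.04 with the test pointing down). Of 17 immediate early genes tested, 2 rose and 1 fell (2 and 1 within the list, camera adjusted p = 0.655). VEGFA (0.46 ± 0.07) rose and CA9 (-0.70 ± 0.11) fell among hypoxia genes. Of 21 hypoxia and glycolysis genes tested, 7 rose and 1 fell (7 and 2 within the list, camera adjusted p = 0.120). Of 13 mitochondrial mRNAs tested, 0 rose and 3 fell (0 and 3 within the list, camera adjusted p = 0.00538, adjusted p = 0.366 with an estimated correlation). Of 26 nuclear OXPHOS genes tested, 0 rose and 1 fell (0 and 0 within the list, camera adjusted p = 0.00987, adjusted p = 0.547 with an estimated correlation). Of 4 nuclear retained RNAs tested, 1 rose and 2 fell (2 and 2 within the list, camera adjusted p = 0.958, median -0.09 with the test pointing up). The test called 2200 genes (1138 rose, 1062 fell). The count was 3509 without the 3 that stand apart. It called 1332 without high-dose replicate 2 and 935 without vehicle replicate 1. Of the 36 genes named here with a call, 36 kept it with each library left out in turn.

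**Figure D2:**
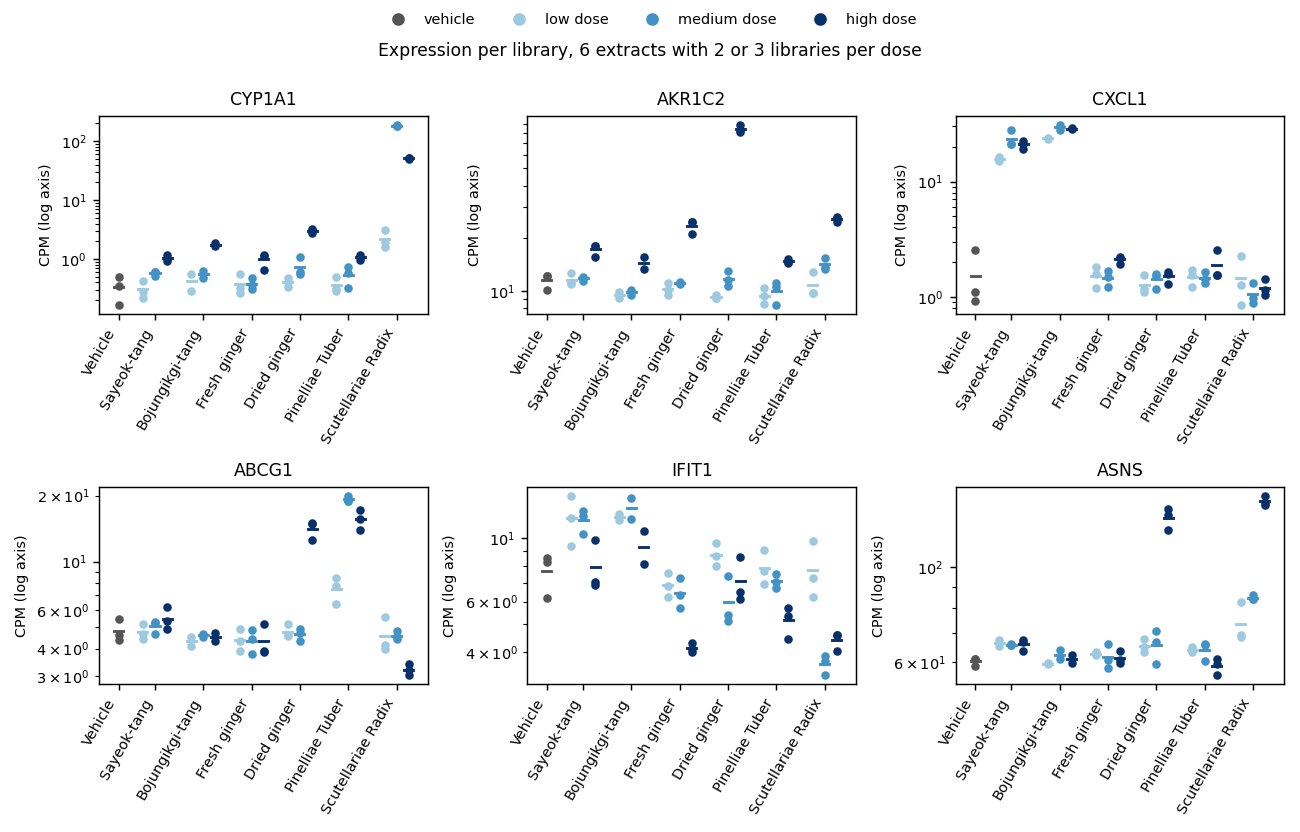
CPM of 6 genes (y axes, log scale) for vehicle and 6 extracts (x axes), with doses by colour, libraries as points and group means as bars. CXCL1 stands above every vehicle library in both water extracts.

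The high dose of dried ginger differed from its low dose in 727 genes (385 rose, 342 fell), led by AKR1C2 (3.17 ± 0.10, adjusted p = 5.6e-27), CYP1A1 (2.88 ± 0.25), AKR1C1 (2.65 ± 0.09), AKR1B10 (1.92 ± 0.09) and ALDH3A1 (1.83 ± 0.10). In all, 22 rose and 0 fell of 24 NRF2 targets tested (24 and 0 within the list, camera adjusted p = 9.9e-72). Among 20 ATF4 and amino acid response genes tested, 13 rose and 0 fell (18 and 0 within the list, camera adjusted p = 5.8e-33). SLC14A1 (-1.65 ± 0.11), CD200 (-1.63 ± 0.09), LINC00261 (-1.31 ± 0.11), NOX1 (-1.29 ± 0.09), and REG4 (-1.24 ± 0.09) fell most. Of NF-kB genes BIRC3 (0.84 ± 0.10) and CXCL8 (0.52 ± 0.12) rose. NF-kB and cytokine genes that rose were 5 and that fell 0 of 16 tested (6 and 0 within the list, camera adjusted p = 4.1e-06). Against vehicle the medium dose called 178 genes and the low dose 334. Of 25 mitosis genes tested at the medium dose, 0 rose and 1 fell (0 and 6 within the list, camera adjusted p = 6.6e-05). At the low dose 38.0% of the called genes rose, and 48.2% of 384 with DESeq2 size factors in the same test. The high against low count was 1832 with only the libraries compared. The medium count was 813 with no low-count filter, 5 with only the libraries compared and 777 without the 3 that stand apart. It was 65 and 61 without medium-dose replicate 1 and 2 and 24, 73 and 315 without vehicle replicate 1, 2 and 3. The low count was 1199 with no low-count filter, 630 with only the libraries compared and 1595 without the 3 that stand apart. It was 44, 20 and 87 without low-dose replicate 1, 2 and 3 and 11, 87 and 804 without vehicle replicate 1, 2 and 3.

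Fresh and dried ginger, forms of the same rhizome, were compared at equal doses. At the high dose 379 genes differed, 105 higher and 274 lower with fresh ginger. AKR1C2 (-1.83 ± 0.09, adjusted p = 6.7e-19), ABCG1 (-1.72 ± 0.12), a cholesterol exporter, AKR1C1 (-1.70 ± 0.09), IGFL2-AS1 (-1.69 ± 0.14) and CYP1A1 (-1.61 ± 0.21) were lower with fresh ginger, and MT2A (1.05 ± 0.26), LINC00261 (0.99 ± 0.11), SLC14A1 (0.94 ± 0.12), DLL4 (0.94 ± 0.15) and CD200 (0.91 ± 0.10) higher. ASNS (-1.09 ± 0.06), TRIB3 (-0.75 ± 0.07), CHAC1 (-1.51 ± 0.16), IRF9 (-0.72 ± 0.13), MX1 (-0.91 ± 0.17) and SQSTM1 (-0.89 ± 0.07) were lower too. ATF4 and amino acid response genes that rose were 0 and that fell 13 of 20 tested (0 and 18 within the list, camera adjusted p = 6.8e-47). Of 24 NRF2 targets tested, 0 rose and 15 fell (0 and 22 within the list, camera adjusted p = 8.8e-44). Interferon genes that rose were 0 and that fell 10 of 20 tested (0 and 17 within the list, camera adjusted p = 4.8e-24). Autophagy and lysosome genes that rose were 0 and that fell 7 of 21 tested (0 and 11 within the list, camera adjusted p = 1.4e-16). MT2A (0.91 to 1.08; fresh high 2, dried high 2 and 3) lost its call with 1 replicate left out. Among 7 metallothionein and zinc genes tested, 4 rose and 0 fell (5 and 0 within the list, camera adjusted p = 8.9e-10). At the medium and low doses edgeR called 0 genes; 439 and 239 had an unadjusted p under 0.05. DESeq2 is not among the settings run there, and with no low-count filter edgeR called 69 and 58. The high-dose count was 760 with only the libraries compared. It was 248 without Zingiberis Rhizoma high-dose replicate 2.

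The high minus low effect of fresh ginger differed from that of dried ginger in 108 genes (24 higher, 84 lower with fresh ginger). AKR1C2 (-1.97 ± 0.14, adjusted p = 1.5e-13), AKR1C1 (-1.75 ± 0.13), ABCG1 (-1.59 ± 0.17), IGFL2-AS1 (-1.49 ± 0.20) and AHNAK2 (-1.29 ± 0.22) had the lower effect with fresh ginger, and CD200 (0.96 ± 0.12), AKAP7 (0.90 ± 0.12), LINC00261 (0.88 ± 0.15), DLL4 (0.84 ± 0.20) and SLC14A1 (0.79 ± 0.15) the higher. ASNS (-1.02 ± 0.08) and TRIB3 (-0.73 ± 0.10) differed too, as did HMOX1 (-0.72 ± 0.14), which degrades haem, and CEACAM6 (-0.67 ± 0.10) and KRT20 (-0.49 ± 0.08) of the enterocyte list. DLL4 (0.73 to 0.85; fresh high 2 and 3, fresh low 1, 2 and 3, dried high 2 and 3, dried low 2 and 3) lost its call with 1 replicate left out. Of 20 ATF4 and amino acid response genes tested, 0 rose and 6 fell (0 and 15 within the list, camera adjusted p = 2.3e-36). Among 24 NRF2 targets tested, 0 rose and 6 fell (0 and 16 within the list, camera adjusted p = 9.8e-39). Enterocyte markers that rose were 0 and that fell 3 of 13 tested (0 and 4 within the list, camera adjusted p = 1.9e-06). The count was 164 with no low-count filter and 320 with only the libraries compared.

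**Figure D3:**
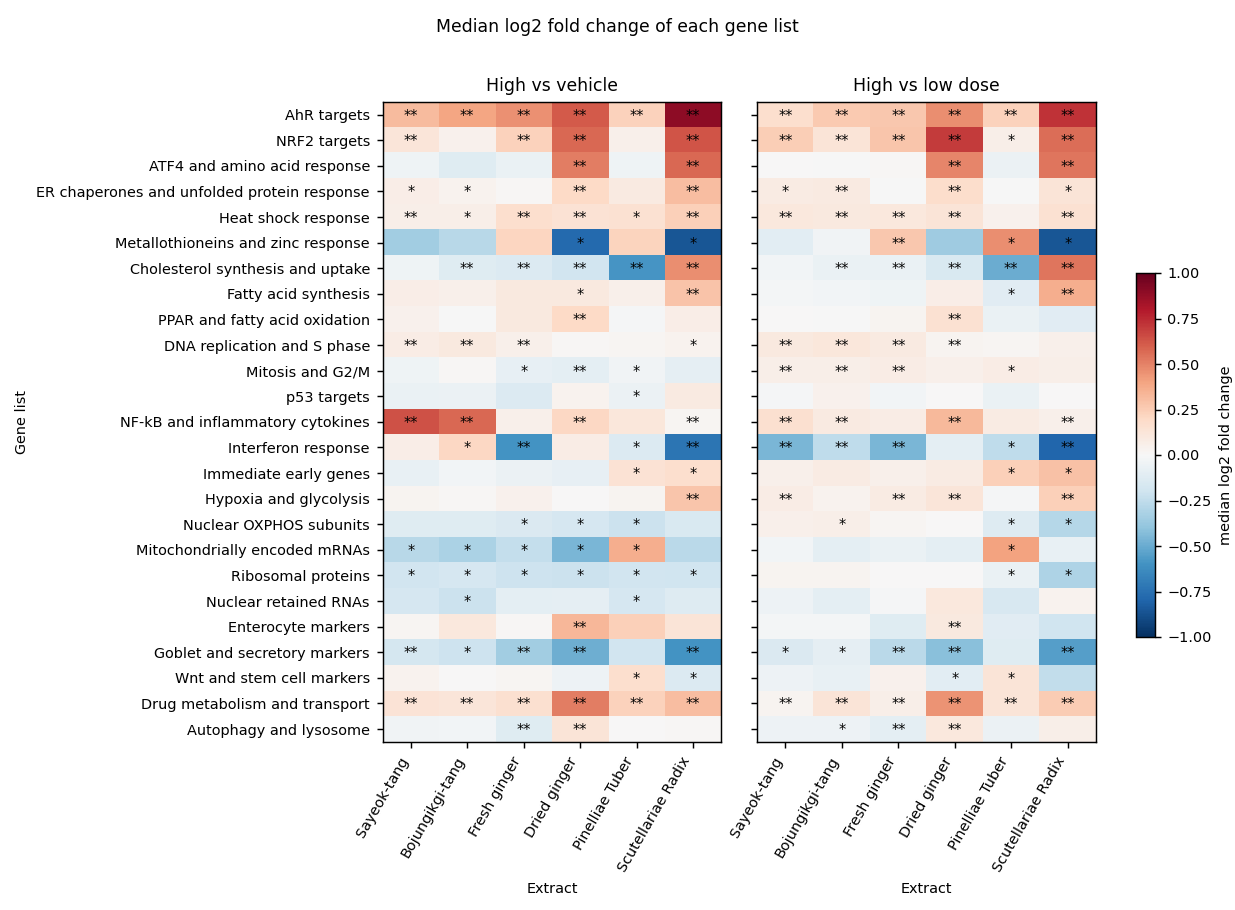
Median log2 fold change (colour) of 25 gene lists (y axis) in 6 extracts (x axis), high dose against vehicle (left) and against low dose (right). A star marks a camera call with the preset correlation and a double star a call also with an estimated one. Against vehicle the cholesterol list has a median of -0.59 in Pinelliae Tuber and 0.46 in Scutellariae Radix.

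Pinelliae Tuber at the high dose lowered genes of cholesterol synthesis (n = 3 against 3). SQLE (-0.54 ± 0.04, adjusted p = 2.9e-12), squalene epoxidase, fell from 802 ± 20.8 to 551 ± 19.5 CPM, with MSMO1 (-1.03 ± 0.10), INSIG1 (-0.72 ± 0.05), LSS (-0.66 ± 0.05) and MVK (-0.80 ± 0.07). Of 21 cholesterol genes tested, 0 rose and 18 fell (0 and 19 within the list, camera adjusted p = 1.8e-46). ABCG1 (1.70 ± 0.12, adjusted p = 6.1e-14) rose from 4.82 ± 0.575 to 15.6 ± 1.70 CPM and ABCA1 (1.01 ± 0.17) rose as well; both export cholesterol and are targets of the liver X receptor. ACSS2 (-0.99 ± 0.07), which makes acetyl-CoA from acetate, fell. Among 11 fatty acid synthesis genes tested, 2 rose and 1 fell (2 and 2 within the list, camera adjusted p = 0.570, median 0.05 with the test pointing down). CYP1A1 (1.75 ± 0.32), CYP1B1 (0.39 ± 0.08), TIPARP (0.40 ± 0.08) and ALDH3A1 (0.41 ± 0.10) rose among AhR targets. In all, 6 rose and 0 fell of 11 AhR targets tested (6 and 0 within the list, camera adjusted p = 2.5e-06). DDIT4 (-0.47 ± 0.10) and TRIB3 (-0.32 ± 0.07) fell in the amino acid response list. Among 20 ATF4 and amino acid response genes tested, 1 rose and 5 fell (1 and 5 within the list, camera adjusted p = 0.113). LGR5 (0.57 ± 0.08) and CD44 (0.24 ± 0.06) rose among stem cell markers, and IFIT2 (-0.58 ± 0.13) and IFIT3 (-0.45 ± 0.11) fell among interferon genes. Among 14 Wnt and stem cell markers tested, 4 rose and 0 fell (4 and 0 within the list, camera adjusted p = 0.00602, adjusted p = 0.302 with an estimated correlation). In all, 0 rose and 3 fell of 20 interferon genes tested (0 and 4 within the list, camera adjusted p = 0.00602, adjusted p = 0.368 with an estimated correlation). PKD1P1 (0.90 ± 0.26), YBX1P1 (0.81 ± 0.17) (pseudogenes, uncertain), LINC03040 (-1.23 ± 0.14), HMGB1P6 (-1.14 ± 0.21) and S100A6 (-1.02 ± 0.23) complete the largest changes.

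High-dose replicate 2 held 14.3% mitochondrial counts, against 9.83% ± 3.90 (SD, n = 3) in its group and 8.23% ± 0.622 in vehicle. Among 13 mitochondrial mRNAs tested, 0 rose and 0 fell (0 and 0 within the list, camera adjusted p = 0.0102, adjusted p = 0.408 with an estimated correlation). Without it the list's median went from 0.364 to -0.125. RPLP1 (-0.92 ± 0.16) fell. Among 32 ribosomal protein genes tested, 0 rose and 7 fell (0 and 13 within the list, camera adjusted p = 3.7e-08, adjusted p = 0.359 with an estimated correlation). Among 26 nuclear OXPHOS genes tested, 0 rose and 3 fell (0 and 8 within the list, camera adjusted p = 1.4e-07, adjusted p = 0.338 with an estimated correlation). The test called 854 genes (371 rose, 483 fell). The count was 1288 with DESeq2, 1712 with no low-count filter, 0 with only the libraries compared and 1547 without the 3 that stand apart, where 0 is from edgeR on the 6 libraries (933 at an unadjusted p under 0.05). It was 2048 and 2009 without high-dose replicate 1 and 3 and 162 and 470 without vehicle replicate 1 and 2. Of the 24 genes named here with a call, 18 kept it with each library left out in turn, and it ended for CD44 (0.17 to 0.20; high 2, vehicle 1), ALDH3A1 (0.18 to 0.38; high 2, vehicle 2), IFIT3 (-0.40; vehicle 1), S100A6 (-0.83; vehicle 1), YBX1P1 (0.28; high 2) and PKD1P1 (0.56 to 0.94; high 2, vehicle 1 and 2).

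Between the high and low doses of Pinelliae Tuber 298 genes differed (193 rose, 105 fell). ACSS2 (-1.02 ± 0.07, adjusted p = 7.1e-14), HMGCS1 (-0.91 ± 0.11), MSMO1 (-0.78 ± 0.10) and LINC03040 (-1.28 ± 0.14) fell. Among 21 cholesterol genes tested, 0 rose and 16 fell (0 and 18 within the list, camera adjusted p = 5.1e-46). ABCG1 (1.05 ± 0.11), CYP1A1 (1.58 ± 0.32), MT2A (0.89 ± 0.25), ATN1 (0.77 ± 0.19) and FOSL1 (0.75 ± 0.19) rose, and so did EGR1 (0.63 ± 0.14) and MYC (0.53 ± 0.14). With 1 replicate left out the call ended for ATN1 (0.10 to 0.79; high 2, low 1, 2 and 3), EGR1 (0.13 to 0.62; high 2, low 1 and 2), MT2A (0.39 to 0.94; high 2, low 1, 2 and 3), MYC (0.03 to 0.54; high 2, low 1, 2 and 3), CYP1A1 (1.44 to 1.49; low 1 and 3) and FOSL1 (0.09 to 0.78; high 2, low 1, 2 and 3). Among 17 immediate early genes tested, 3 rose and 0 fell (9 and 1 within the list, camera adjusted p = 2.3e-04, adjusted p = 0.206 with an estimated correlation). Against vehicle the medium dose called 354 genes, with ABCG1 (2.00 ± 0.11), ABCA1 (1.29 ± 0.16) and MYLIP (0.72 ± 0.07), an LXR target. Cholesterol genes that rose at the medium dose were 0 and that fell 11 of 21 tested (0 and 17 within the list, camera adjusted p = 1.3e-18). The low dose called 91, among them ABCG1 (0.65 ± 0.12). ABCG1 (0.56 to 0.57; low 3, vehicle 2) lost its call with 1 replicate left out. The high against low count was 698 with DESeq2, 1422 with no low-count filter, 0 with only the libraries compared, 124 with a replicate block within code set and 130 without the 3 that stand apart, where 0 is from edgeR on the 6 libraries (403 at an unadjusted p under 0.05). It was 2775, 65 and 2588 without high-dose replicate 1, 2 and 3 and 61, 68 and 83 without low-dose replicate 1, 2 and 3. The medium count was 971 with no low-count filter, 882 with only the libraries compared and 1563 without the 3 that stand apart. It was 72, 87 and 73 without medium-dose replicate 1, 2 and 3 and 36, 107 and 676 without vehicle replicate 1, 2 and 3. The low count was 406 with no low-count filter, 5 with only the libraries compared and 832 without the 3 that stand apart. It was 30, 21 and 13 without low-dose replicate 1, 2 and 3 and 13, 21 and 197 without vehicle replicate 1, 2 and 3.

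Scutellariae Radix at the high dose moved the most genes of the 18 groups with 2 or 3 libraries, 1920 up and 2035 down (n = 3 against 3). CYP1A1 (7.31 ± 0.19, adjusted p = 9.9e-30), which oxidises polycyclic aromatics, went from 0.335 ± 0.163 to 51.1 ± 1.3 CPM (ENSG00000140465, chromosome 15, 74719542 to 74725610). CYP1B1 (2.64 ± 0.08), TIPARP (1.53 ± 0.08) and ALDH1A3 (1.13 ± 0.07) rose with it. Among 11 AhR targets tested, 10 rose and 0 fell (10 and 0 within the list, camera adjusted p = 3.5e-22). SLC7A11 (1.73 ± 0.12), the cystine transporter, AKR1B10 (1.43 ± 0.09), GCLC (1.12 ± 0.07) and HMOX1 (1.35 ± 0.10) rose among NRF2 targets. NRF2 targets that rose were 20 and that fell 0 of 24 tested (21 and 0 within the list, camera adjusted p = 2.1e-26). ASNS (1.24 ± 0.06) reached 143 ± 3.75 CPM, and TRIB3 (1.26 ± 0.07), ATF3 (1.69 ± 0.14) and DDIT4 (1.07 ± 0.09) rose. In all, 14 rose and 0 fell of 20 ATF4 and amino acid response genes tested (16 and 0 within the list, camera adjusted p = 3.7e-18). Cholesterol genes rose: SQLE (0.71 ± 0.04) reached 1308 ± 44.0 CPM from 802 ± 20.8 CPM, with INSIG1 (0.71 ± 0.05), SC5D (0.76 ± 0.06) and LSS (0.46 ± 0.05), and ACSS2 (1.34 ± 0.06) rose among fatty acid genes. In all, 20 rose and 0 fell of 21 cholesterol genes tested (20 and 0 within the list, camera adjusted p = 6.5e-22). Fatty acid synthesis genes that rose were 6 and that fell 1 of 11 tested (6 and 1 within the list, camera adjusted p = 2.8e-06). SLC2A1 (0.69 ± 0.04), VEGFA (0.69 ± 0.07) and HK2 (0.64 ± 0.08) rose among hypoxia and glycolysis genes. Among 21 hypoxia and glycolysis genes tested, 11 rose and 1 fell (11 and 1 within the list, camera adjusted p = 1.2e-05).

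Interferon genes fell, MX1 (-1.52 ± 0.18) from 9.62 ± 0.991 to 3.34 ± 0.234 CPM, with IRF9 (-1.17 ± 0.14), CMPK2 (-1.56 ± 0.22) and IFIT3 (-0.73 ± 0.11). Of 20 interferon genes tested, 0 rose and 16 fell (0 and 19 within the list, camera adjusted p = 4.8e-12). Secretory markers REG4 (-1.03 ± 0.09) and ATOH1 (-1.48 ± 0.20) fell. Of 13 secretory markers tested, 0 rose and 8 fell (0 and 9 within the list, camera adjusted p = 2.4e-05). NOX1 (-2.04 ± 0.10), CD200 (-2.04 ± 0.10), GABRP (-1.97 ± 0.09), SPEG (-1.91 ± 0.20) and DLL4 (-1.79 ± 0.15) fell most. AHNAK2 (1.83 ± 0.15) and GPAT3 (1.66 ± 0.08) were among the largest rises. The p53 list split, CDKN1A (0.91 ± 0.08) and GDF15 (0.89 ± 0.12) up and BTG2 (-1.31 ± 0.09) and SESN1 (-0.88 ± 0.08) down. Among 18 p53 targets tested, 6 rose and 4 fell (8 and 4 within the list, camera adjusted p = 0.465). DUSP5 (1.42 ± 0.11) and PHLDA1 (0.72 ± 0.05) rose among immediate early genes, DNAJB9 (0.91 ± 0.10) and HSPA5 (0.42 ± 0.06) among ER chaperones, HSPH1 (0.58 ± 0.05) among heat shock genes, and CXCL8 (1.09 ± 0.12) and NFKB2 (0.48 ± 0.09) in the NF-kB list. Immediate early genes that rose were 7 and that fell 1 of 17 tested (7 and 1 within the list, camera adjusted p = 1.2e-04, adjusted p = 0.100 with an estimated correlation). Among 17 ER chaperone genes tested, 10 rose and 0 fell (10 and 0 within the list, camera adjusted p = 1.2e-06). Heat shock genes that rose were 7 and that fell 1 of 15 tested (11 and 1 within the list, camera adjusted p = 1.2e-05). Of 16 NF-kB and cytokine genes tested, 6 rose and 1 fell (6 and 1 within the list, camera adjusted p = 0.0237). Metallothionein MT1X (-1.20 ± 0.24) fell. Metallothionein and zinc genes that rose were 1 and that fell 5 of 7 tested (1 and 5 within the list, camera adjusted p = 0.0271, adjusted p = 0.184 with an estimated correlation). Of 2 tested fibroblast markers neither was called, too few for camera, and of leukocyte markers CD14 (-1.08 ± 0.19) fell. Of 2 fibroblast markers tested, 0 rose and 0 fell (1 and 0 within the list). Of 3 leukocyte markers tested, 0 rose and 1 fell (0 and 1 within the list, camera adjusted p = 0.268). The test called 3955 genes, and 2517 without vehicle replicate 1. Of the 46 genes named here with a call, 46 kept it with each library left out in turn.

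High against low dose of Scutellariae Radix called 3764 genes (1797 rose, 1967 fell), with CYP1A1 (4.50 ± 0.15, adjusted p = 7.4e-26), AHNAK2 (2.11 ± 0.16), SLC7A11 (1.61 ± 0.12), DUSP5 (1.54 ± 0.12) and CYP1B1 (1.51 ± 0.07) rising and GABRP (-2.03 ± 0.09), NOX1 (-1.97 ± 0.10), CD200 (-1.80 ± 0.10), SPEG (-1.79 ± 0.20) and PLAAT4 (-1.71 ± 0.15) falling. Among 20 interferon genes tested, 0 rose and 16 fell (0 and 18 within the list, camera adjusted p = 8.7e-14). Against vehicle, CYP1A1 read 9.15 ± 0.19 at the medium dose and 2.81 ± 0.28 at the low dose; the medium and high doses were not tested against each other. ALDH1A3 (2.59 ± 0.07), CYP1B1 (3.38 ± 0.08) and SLC22A3 (1.75 ± 0.08) were other rises at the medium dose, and DLL4 (-1.44 ± 0.14) and IFIT1 (-1.07 ± 0.17) falls. The medium dose called 1598 genes and the low dose 64, among them CYP1B1 (1.12 ± 0.08). Low-dose replicate 3 held 9.20% ribosomal protein counts, against 6.77% ± 2.10 (SD, n = 3) in its group. The high against low count was 310 with only the libraries compared. It was 2433 without high-dose replicate 2 and 2215 without low-dose replicate 3. The medium count was 2464 with only the libraries compared and 3020 without the 3 that stand apart. It was 900 and 878 without medium-dose replicate 2 and 3 and 677 and 1037 without vehicle replicate 1 and 2. The low count was 378 with no low-count filter, 0 with only the libraries compared and 579 without the 3 that stand apart, where 0 is from edgeR on the 6 libraries (527 at an unadjusted p under 0.05). It was 406, 231 and 748 without low-dose replicate 1, 2 and 3 and 29, 17 and 30 without vehicle replicate 1, 2 and 3.

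Scutellariae Radix and Pinelliae Tuber, compared directly at the high dose, differed in 3825 genes (1659 higher, 2166 lower with Scutellariae Radix). The cholesterol list parted them most by camera, with SQLE (1.25 ± 0.04, adjusted p = 2.0e-25), INSIG1 (1.43 ± 0.05) and CYP51A1 (1.39 ± 0.08) higher, and ACSS2 (2.33 ± 0.07) and LINC03040 (2.11 ± 0.13) higher too. Of 21 cholesterol genes tested, 20 rose and 0 fell (20 and 0 within the list, camera adjusted p = 1.7e-52). ABCG1 (-2.28 ± 0.12) was lower with Scutellariae Radix, as were GABRP (-2.51 ± 0.09), SPEG (-2.16 ± 0.20), NOX1 (-1.91 ± 0.10) and ATP6V1B1 (-1.80 ± 0.13). CYP1A1 (5.55 ± 0.16) and CYP1B1 (2.25 ± 0.08) were higher, HMOX1 (1.38 ± 0.10) as well, and IRF9 (-1.05 ± 0.14) and MX1 (-1.31 ± 0.19) lower. AhR targets that rose were 8 and that fell 0 of 11 tested (9 and 0 within the list, camera adjusted p = 4.8e-18). In all, 21 rose and 0 fell of 24 NRF2 targets tested (21 and 0 within the list, camera adjusted p = 3.6e-27). In all, 1 rose and 13 fell of 20 interferon genes tested (1 and 16 within the list, camera adjusted p = 3.1e-07, adjusted p = 0.0507 with an estimated correlation). Mitochondrial mRNAs that rose were 0 and that fell 10 of 13 tested (0 and 12 within the list, camera adjusted p = 0.00125, adjusted p = 0.272 with an estimated correlation). Without Pinelliae Tuber replicate 2 the call held for 1 of them, and the list's median went from -0.615 to -0.081. The count was 379 with only the libraries compared. It was 2186 without Pinelliae Tuber high-dose replicate 2.

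Dose effects were compared between extracts by their high minus low changes, which share no library. In 6 of 6 extracts AKR1B10, AKR1C2, ALDH3A1 and CYP1A1 rose and SLC6A20 fell. With 1 library left out, each lost its call in Bojungikgi-tang. So did CYP1A1 and AKR1B10 in Pinelliae Tuber, CYP1A1 and SLC6A20 in Sayeok-tang and CYP1A1 in fresh ginger. At the high dose CYP1A1 read 49.8 to 52.4 CPM in Scutellariae Radix but 0.64 to 3.18 CPM in the rest of the 6. Dried ginger and Scutellariae Radix had 278 genes that rose in both (41.3 for independent lists), 257 that fell in both (40.1) and 15 with opposite calls. Pinelliae Tuber and Scutellariae Radix had 50 that rose in both (20.7 for independent lists), 28 that fell in both (12.3) and 44 opposite, but 11 to 17, 7 to 8 and 27 to 31 without any 1 of 4 Pinelliae Tuber libraries. Fresh and dried ginger had 29 and 31 in common (0.71 and 1.04 for independent lists) and 2 opposite, but 13 to 19 and 11 to 21 in common without 1 fresh ginger library. Across genes, which are not independent, the changes correlated with a median of 0.0640 over the 15 pairs of extracts (0.367 with an average log2 CPM above 2).

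Coptidis Rhizoma has n = 1 per dose, so single libraries have no replicate check and no p-value. Its ratios are log2 against the vehicle mean at the high, medium and low dose. The ATF4 and amino acid response list had medians of 2.71, 1.17 and 0.27, each above 10000 random lists matched on expression (percentile 100). Percentiles ignore correlation of members and are no test of the extract. AhR targets had medians of 1.53, 0.85 and 0.28 (percentiles 100, 100 and 99.99), and CYP1A1 read 250 CPM at the high dose against 0.335 ± 0.163 CPM in vehicle. ASNS read 792 CPM. The interferon list had medians of 1.85, 0.23 and 0.21, the cholesterol list -1.29, -0.34 and -0.16, the secretory list -0.93, -0.50 and -0.12, and the replication list -1.51, -0.04 and -0.05. Mitochondrial mRNAs had medians of -2.05, -1.62 and -0.86 (percentile 0 at each dose), while the ribosomal RNA MT-RNR1 read 1.14, 3.34 and 3.99. By the rule for single libraries MT-RNR1 rose and 6 genes fell at all 3 doses. MT-ATP8 (-2.55, -1.81 and -1.43), MT-CO2 (-2.08, -1.81 and -1.17), MT-ND3 (-2.07, -2.12 and -1.04), MT-ATP6 (-2.04, -1.64 and -1.18) and MT-CO3 (-1.87, -1.97 and -1.64) were the 5 largest falls. The ratio of mitochondrial rRNA to mRNA counts was 0.799, 1.81 and 1.85 at the high, medium and low dose, and 0.148 to 0.164 in vehicle.

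Tested as 1 group of 3 doses against vehicle, edgeR called 4 genes, all of which fell, and 1859 had an unadjusted p under 0.05. MT-CO3 (-1.83 ± 0.18, adjusted p = 0.0418) was the one the rule for naming picks. MT-CO3 (-1.93 to -1.70; low 1, medium 1, vehicle 1, 2 and 3) lost its call with 1 replicate left out. The other 3, named after their values were seen, have Ensembl IDs but no symbol: ENSG00000280614 (-2.16 ± 0.14), ENSG00000280800 (-2.25 ± 0.14) and ENSG00000281181 (-2.16 ± 0.14). Doses in this group differ widely, as CYP1A1 (8.15 ± 1.90) shows by its SE. ATF4 and amino acid response genes that rose were 0 and that fell 0 of 20 tested (19 and 0 within the list, camera adjusted p = 1.9e-09, adjusted p = 0.561 with an estimated correlation). Of 13 mitochondrial mRNAs tested, 0 rose and 1 fell (0 and 8 within the list, camera adjusted p = 1.1e-10, adjusted p = 0.561 with an estimated correlation). The count was 80 with DESeq2 and 8610 for the high-dose library alone, which is assumed to vary like the other groups. It was 8 without the high, 0 without the medium and 3 without the low dose, 0 without vehicle replicate 1, and 3 without vehicle replicate 2 or 3.

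**Figure D4:**
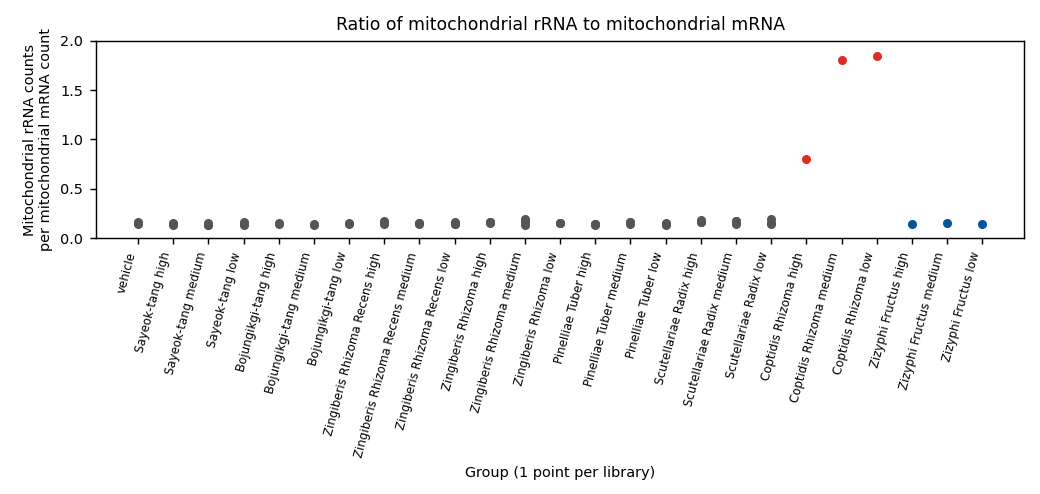
Ratio of mitochondrial rRNA to mitochondrial mRNA counts (y axis) in each of the 60 libraries (points, by group on the x axis). The Coptidis Rhizoma libraries stand above all others.

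Zizyphi Fructus, also with n = 1 per dose, had 1 gene with a log2 ratio above 1 at all 3 doses, ATP6V1G2-DDX39B (2.63, 1.34 and 1.502), and 1 below -1, BCYRN1 (-1.01, -1.04 and -1.10), which was lower in 14 of the 18 groups too. As 1 group of 3 doses it called 426 genes (189 rose, 237 fell). PGGHG (0.73 ± 0.06, adjusted p = 5.9e-04), ABCA1 (0.72 ± 0.13), CCDC78 (0.80 ± 0.11), GUSBP11 (0.94 ± 0.16) and PKD1P1 (0.87 ± 0.10) rose, the last pair copies of GUSB and PKD1 and uncertain. MALAT1 (-0.81 ± 0.07, adjusted p = 0.00112), RPLP1 (-0.81 ± 0.15), S100A6 (-0.74 ± 0.14), FAM215B (-0.89 ± 0.12) and RPL15P3 (-0.98 ± 0.12) (a pseudogene, uncertain) fell. Mitosis genes PLK1 (-0.37 ± 0.05), CCNB1 (-0.31 ± 0.05) and AURKA (-0.27 ± 0.05) fell, LGR5 (0.42 ± 0.06) rose and REG4 (-0.43 ± 0.08) fell. Of the 15 named, PGGHG and MALAT1 kept the call with each library left out. The other 13 lost it without any 1 dose (adjusted p = 0.0739 to 0.188), all but RPL15P3 without vehicle replicate 2, and RPLP1 and S100A6 without vehicle replicate 1 too. Among 25 mitosis genes tested, 0 rose and 8 fell (0 and 16 within the list, camera adjusted p = 3.9e-08, adjusted p = 0.0707 with an estimated correlation). Ribosomal protein genes that rose were 0 and that fell 1 of 32 tested (0 and 14 within the list, camera adjusted p = 4.5e-09, adjusted p = 0.792 with an estimated correlation). The count was 1351 with DESeq2, 1740 with no low-count filter. It was 9, 8 and 8 without the high, medium and low dose and 2089, 8 and 2162 without vehicle replicate 1, 2 and 3.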

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

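The tests of code sets, leukocyte RNA, the vehicle level of NF-kB genes, vehicle replicate 1 and RNA without a poly(A) tail in the high-dose library alone were chosen after the results were seen, and those of vehicle against all treated libraries, transcript length and RNA without a poly(A) tail were set before their values were seen. The results below stand out because 2 extracts given alike differ in a test of the difference itself. The high minus low effect differed between fresh and dried ginger in 108 genes, and the high-dose groups of these differed in 379. Scutellariae Radix and Pinelliae Tuber differed in 3825 genes at the high dose, and the cholesterol list by a median log2 difference of 1.08.

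The first pattern weighed is the NF-kB list, above vehicle in both water extracts at each dose. Its 7 members called in both (CXCL8, CXCL1, CXCL2, CXCL3, CCL20, ICAM1 and BIRC3) had medians of 1.77 and 2.09 at the low dose for Sayeok-tang and Bojungikgi-tang. Vehicle libraries that read low are excluded, since the highest median in 4 ethanol extracts at the low dose was 0.08. RNA of leukocytes is excluded too, since 7 markers at or under 1 CPM in vehicle summed to at most 0.33 CPM in a water extract library. A difference between code sets cannot be told apart from water extraction, since the lowest median of 1.774 lies in the code set that holds both water extracts and no other sample.

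The second pattern is the count of genes called at the low dose against vehicle in both ginger extracts and Sayeok-tang. A difference of the vehicle libraries from all treated ones stays open. The mean of these 3 low-dose groups against that of Pinelliae Tuber and Scutellariae Radix called 10 genes, under the 50 set for it, but 3932 had an unadjusted p under 0.05 (a bound added after it was seen), against 3515 to 3836 for each of the 3 with vehicle. Vehicle replicate 1 with its ribosomal protein share stays open. Without it alone the counts for Sayeok-tang, fresh ginger and dried ginger went from 554, 520 and 334 to 55, 17 and 11, and without vehicle replicate 3 to 1009, 1187 and 804, but without the 3 libraries that stand apart, which include it, the lowest was 1595. Transcript length stays open, with r of at most 0.231 in size between log2 fold change and log2 length. All contrasts with vehicle share its libraries, so calls at any dose may hold a part that is no effect of the extract. High against low dose holds no vehicle library.

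The third pattern is mitochondrial RNA in Coptidis Rhizoma, with rRNA up and mRNA down. A difference between code sets is excluded by Zizyphi Fructus in the same set, whose highest ratio of rRNA to mRNA was 0.1568 against 0.148 to 0.164 in vehicle. Carry-over of RNA without a poly(A) tail is excluded at the medium and low dose, since 31 such nuclear RNAs had median log2 ratios of -0.27 and -0.33 where mitochondrial rRNA read 2.49 and 3.47. At the high dose it stays open for the rise of rRNA, since these RNAs rose by 0.476 against 0.773. No test set an effect of the extract against the quality or handling of these 3 libraries, so both stay open, with n = 1 per dose.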

How the results depend on the processing

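Besides the fits added above, those without 1 library for the mitochondrial list and shared genes were chosen after the data were seen. Other tests came before. Counts of calls per comparison depend on processing. Directions were followed for named genes only, many of them picked because their libraries do not overlap, so they cannot be set against the counts. Those below lie over 1.5 times from the main ones, all others within. DESeq2 size factors moved no count so far. The cause was not tested, except that fewer libraries leave fewer degrees of freedom. DESeq2 gave against vehicle Bojungikgi-tang high 178, Pinelliae Tuber high 1288. It gave between high and low dose Sayeok-tang 104, Bojungikgi-tang 17, fresh ginger 143 and Pinelliae Tuber 698. It gave Coptidis Rhizoma 80 and Zizyphi Fructus 1351. No low-count filter gave against vehicle Sayeok-tang high 1016, medium 451 and low 1417, Bojungikgi-tang high 367, medium 1009 and low 586. For fresh ginger medium 1478 and low 1482. For dried ginger medium 813 and low 1199. For Pinelliae Tuber high 1712, medium 971 and low 406. For Scutellariae Radix low 378. It gave between high and low dose Sayeok-tang 124, Bojungikgi-tang 70, fresh ginger 140 and Pinelliae Tuber 1422. It gave ginger medium 69, ginger low 58, ginger interaction 164, Sayeok-tang against Bojungikgi-tang 40 and Zizyphi Fructus 1740. Only the libraries compared gave against vehicle Sayeok-tang low 1059, Bojungikgi-tang high 30, medium 41 and low 29. For fresh ginger medium 29. For dried ginger medium 5 and low 630. For Pinelliae Tuber high 0, medium 882 and low 5. For Scutellariae Radix medium 2464 and low 0. It gave between high and low dose Sayeok-tang 519, Bojungikgi-tang 323, fresh ginger 214, dried ginger 1832, Pinelliae Tuber 0 and Scutellariae Radix 310. It gave ginger high 760, ginger interaction 320, Scutellariae Radix against Pinelliae Tuber 379 and Sayeok-tang against Bojungikgi-tang 14. Leaving out the 3 libraries that stand apart gave against vehicle Sayeok-tang high 1368, medium 554 and low 1724, Bojungikgi-tang high 412, medium 1595 and low 444. For fresh ginger high 2435, medium 1667 and low 2026. For dried ginger high 3509, medium 777 and low 1595. For Pinelliae Tuber high 1547, medium 1563 and low 832. For Scutellariae Radix medium 3020 and low 579. It gave between high and low dose Pinelliae Tuber 130. The high-dose library alone gave in the other comparisons Coptidis Rhizoma 8610 and Zizyphi Fructus 4. A replicate block within code set gave between high and low dose Pinelliae Tuber 124. It gave Sayeok-tang against Bojungikgi-tang 0. The lowest and highest counts with 1 library left out were against vehicle Sayeok-tang high 140 to 645, medium 51 to 195 and low 55 to 1009, Bojungikgi-tang high 34 to 141, medium 30 to 603 and low 22 to 131. For fresh ginger high 181 to 1479, medium 10 to 966 and low 17 to 1187. For dried ginger high 935 to 2445, medium 24 to 315 and low 11 to 804. For Pinelliae Tuber high 162 to 2048, medium 36 to 676 and low 13 to 197. For Scutellariae Radix high 2517 to 3983, medium 677 to 1803 and low 17 to 748. They were between high and low dose Sayeok-tang 19 to 27, Bojungikgi-tang 2 to 6, fresh ginger 28 to 50, Pinelliae Tuber 61 to 2775 and Scutellariae Radix 2215 to 5144. They were in the other comparisons ginger high 248 to 285, Scutellariae Radix against Pinelliae Tuber 2186 to 5267, Sayeok-tang against Bojungikgi-tang 0 to 1, Coptidis Rhizoma 0 to 8 and Zizyphi Fructus 8 to 2162. Where 1 library of Bojungikgi-tang is left, it is assumed to vary like the other groups.

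At the high dose against vehicle and low dose, camera called 163 of 312 lists with the preset correlation and 108 with an estimated one, and the median correlation of dose effects went from 0.0640 to 0.367 among genes with an average log2 CPM above 2. The replicate block (plain) moved no count over 1.5 times, and a replicate block within code set moved no other count so far. The median of the mitochondrial list in Pinelliae Tuber high dose against vehicle (0.364) was -0.125 and 0.569 without its replicates 2 and 3. Genes called alike by dose with Scutellariae Radix (78) were 18 to 394 without 1 library of Pinelliae Tuber, and in the ginger extracts (60) 24 to 38 without 1 of fresh ginger. Of the values of named genes under other settings, 4029 in all, 3653 kept their direction and side of the threshold, 7 gained a call (1 with DESeq2, 1 with high-dose library alone, pooled spread, 1 with no low-count filter, 3 only the libraries compared and 1 without the 3 that stand apart), 369 lost the call (5 with DESeq2, 1 with DESeq2 size factors, 15 with high-dose library alone, pooled spread, 244 with a library left out, 15 with no low-count filter, 65 only the libraries compared, 6 with replicate block, 6 with a replicate block within code set and 12 without the 3 that stand apart).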

Other observations

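The tests of other splits of the libraries were chosen after the results were seen. In each, the 6 libraries of a comparison were divided anew into groups of 3 in each of 10 ways, with the fit on those libraries alone. With 10 splits no share under 0.05 can be reached. The real split called 417 genes in Sayeok-tang high dose against vehicle (highest other 0), 93 at the medium dose (0) and 1059 at the low dose (1). Fresh ginger called 1185 (1), 29 (1) and 670 (0), dried ginger 2687 (0), 5 (1) and 630 (0), Pinelliae Tuber 0 (0), 882 (1) and 5 (0), and Scutellariae Radix 4434 (0), 2464 (1) and 0 (0). High against low dose gave 519 (3) in Sayeok-tang, 214 (3) in fresh ginger, 1832 (0) in dried ginger, 0 (0) in Pinelliae Tuber and 310 (0) in Scutellariae Radix. Fresh against dried ginger gave 760 (0) at the high, 0 (1) at the medium and 0 (13) at the low dose, and Scutellariae Radix against Pinelliae Tuber 379 (0). Coptidis Rhizoma gave 4 (0) and Zizyphi Fructus 426 (1). The real split alone reached its count in all of these except those with 0 genes, where 10 of 10 did. Where replicate numbers pair the samples, the other splits that part 3 pairs called 0 genes in Pinelliae Tuber at the medium and low dose and 0 in the ginger extracts at the low dose.

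For the ginger interaction, 6 of 100 draws of labels within each extract called as many genes as the real one (320), the real one included, and the highest other called 1037. The other draws with as many kept or exchanged dried ginger's dose groups whole, and so hold its difference between doses, while 89 draws that mixed them called at most 10. The draws therefore do not decide whether chance gives a count of this size.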
